A study of Apis cerana cerana with 5 samples.

How the data were processed

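Gene expression was measured by RNA sequencing in 5 libraries made from heads of Apis cerana cerana workers, with 1 library for each kind of worker. Per the labels' protocols, total RNA was extracted with guanidinium hydrochloride, cleared of DNA and made into libraries by standard Illumina methods. Per the submitters' processing notes, Bowtie2 2.0.6, TopHat2 2.0.9 and edgeR were used. The genome build, the annotation, the read counter and the edgeR version are not given in the sources used here. How reads that match several similar genes were counted, and whether strand was used, is also not given in the sources used here, so genes with near-identical copies are uncertain.

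The deposited table held 10651 genes and 1 column of values per library, and every column was matched to its sample by the sample's title. The file header does not name the unit. The values were taken to be RPKM as deposited by the authors (reads scaled to gene length and to library total), because within a gene the values of the libraries were whole multiples of 1 read's worth, and what 1 read was worth differed between genes; the authors may call the unit FPKM. From these steps a total for each library and a length for each gene were found that turned the values into whole reads. Values of all 9897 genes above 0 in at least 1 library (100%) came out whole, within a tolerance of 0.0001 reads plus 3e-08 of the read number, and none lay farther than 0.000164 reads from a whole number. The same search accepted 0 of 1000 genes whose values had been moved at random by up to 1%. These were drawn from the 8590 genes above 0 in every library. Genes at 0 in some library were not checked this way, and fewer values are more easily turned into whole reads. The reads are the smallest whole numbers that fit a gene, so a gene whose reads and length share a common factor is understated; reads summed over genes made up 99.3% to 99.4% of the totals. The totals were between 4628566 and 6859109 reads, a 1.48-fold range. The other 754 genes were at 0 in every library. The median recovered length was 2419 bases, and 40.3% of the lengths were multiples of 3. A count of 3 reads, the limit that a count of 0 allows, was between 4.37e-05% and 6.48e-05% of a library.

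The table of reference genes used here (assembly AcerK_1.0, 13145 rows) matched 0 of the 10651 IDs, so no gene has a name or a position here. A total of 27 gene lists had been fixed before the data were examined, among them royal jelly proteins, the circadian clock and markers of gland, muscle, eye, fat body, haemocytes, glia, neurons and cuticle. With no names, 0 of the 27 lists had a matched gene, and no list was tested. The rule for named genes, also fixed beforehand, allows at most 2 rising and 2 falling IDs per comparison where genes have no names. For role these were the genes with the largest log2 ratio, taken as the smaller of those at 7 and 22 days with the same sign, among genes at 10 RPKM or more in at least 1 library. For age they were the genes with the smallest p in each direction. The most abundant gene of each library, by reads and by RPKM, was named for its share of reads.

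The design fixed beforehand assumed counts for the main tests and gave a second form for normalized values, which was used because the table holds RPKM. Role (2 nurse and 3 forager libraries) and age class (2 libraries aged 7 days and 3 aged 18 or 22 days) were fitted together over the 5 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(RPKM + 1), for the 7758 genes at 1 RPKM or more in at least 2 libraries. Adjusted p are Benjamini-Hochberg values with a threshold of 0.05. The fit has 2 residual degrees of freedom, which hold the difference between the 18-day and 22-day foragers and the interaction of role and age. Fold changes on this scale understate the change of low genes. Each pair of libraries, and the 3 contrasts of the 4 libraries aged 7 and 22 days, were compared without a test, as log2 ratios of TMM-scaled RPKM with 1 added, and genes at or beyond 2-fold were counted. TMM factors were computed on RPKM without weights, trimming 30% of the log ratios and 5% of the mean levels at each end. They were 0.791 for the 7-day nurses, 1.07 for the 18-day foragers, 1.21 for the 22-day foragers, 0.929 for the precocious foragers and 1.05 for the 22-day nurses, and values were divided by them. Counting intervals are exact 95% intervals, binomial for shares and conditional binomial for folds, computed from the recovered reads with SciPy 1.17.1 in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6. Folds in the text are ratios of TMM-scaled reads with nothing added.

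The limma fit was tested on simulated data for the role comparison, with 200 changed genes drawn from the real genes' levels and library totals at a dispersion of 0.05. Of changed genes it recovered 17.2% at 2-fold (7739 genes run), 94.9% at 4-fold (7701 genes run) and 99.5% at 8-fold (7698 genes run), and it made 0 calls among 7767 genes with no change. Of the calls at 2-fold, 20.9% were false, and at 4-fold 7.43%. The simulated libraries had the same dispersion for every gene and no age effect, interaction or library-wide shift. These rates therefore need not hold for the real libraries.

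Alternatives were other scalings (TMM, median of ratios, and totals without the 50 most abundant genes), no filter or a filter of 5 RPKM, pseudocounts of 0.1 and 5, limma-voom on the recovered reads, each term alone, and each library left out in turn. TMM and median-of-ratios scaling of the role and age fits, the totals without abundant genes, and limma-voom on recovered reads were chosen after seeing the data.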

Results

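RNA was sequenced from whole heads of workers of the Chinese honey bee, Apis cerana cerana. Worker honey bees usually nurse the brood when young, feeding larvae with secretions of glands in the head, and collect nectar and pollen outside the nest when older. The 5 libraries stood for 5 kinds of worker, with 1 library each. They were normal nurses aged 7 days, normal foragers aged 18 days, normal foragers aged 22 days, precocious foragers aged 7 days, and nurses aged 22 days that the labels describe as either overaged or reverted. Foragers and nurses of the same age could therefore be compared at 7 and at 22 days, and workers of different age within each task. Library totals recovered from the values were 4628566 reads for the 7-day nurses, 4899287 for the 18-day foragers, 6564840 for the 22-day foragers, 6176973 for the precocious foragers and 6859109 for the 22-day nurses. Of the 10651 genes listed, 9897 had a value above 0 in at least 1 library, and 7758 reached 1 RPKM in at least 2 libraries and were compared. The files give gene IDs without names, so genes are identified by ID. No group had a replicate, so a comparison of a single pair of libraries has no replicate check. Nothing says which colonies or pools the bees came from, so differences between these libraries may be technical. The limma p-values below measure no replicate spread. The fit over the 5 libraries has 2 residual degrees of freedom. They hold the difference between the 18-day and 22-day foragers and the interaction of role and age. Limma also draws each gene's spread to a common trend, weighted on the deposited values as 13.3 prior degrees of freedom.

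The 2 normal forager libraries, aged 18 and 22 days, were the most alike of the 10 pairs, with a root mean square log2 difference of 0.375 over the 7758 genes. The 7-day nurses differed most from the 22-day foragers, at 0.709, and from the 18-day foragers, at 0.692. The 22-day nurses lay closer to the 18-day foragers, at 0.515, than to the 7-day nurses, at 0.590. The precocious foragers differed by 0.603 from the 18-day foragers, 0.632 from the 22-day nurses, 0.676 from the 22-day foragers and 0.681 from the 7-day nurses. As deposited, they differed more from the 22-day foragers, at 0.721, than from the 7-day nurses, at 0.689. On the first principal component, with 41.6% of the variance, the 7-day nurses scored -34.2 and the normal foragers 21.7 at 18 days and 25.9 at 22 days, while the precocious foragers, at -9.87, and the 22-day nurses, at -3.54, fell between them. The second component, with 30.9%, set the precocious foragers, at 36.7, apart from the other libraries, which scored between -16.4 and -1.20.

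**Figure D1:**
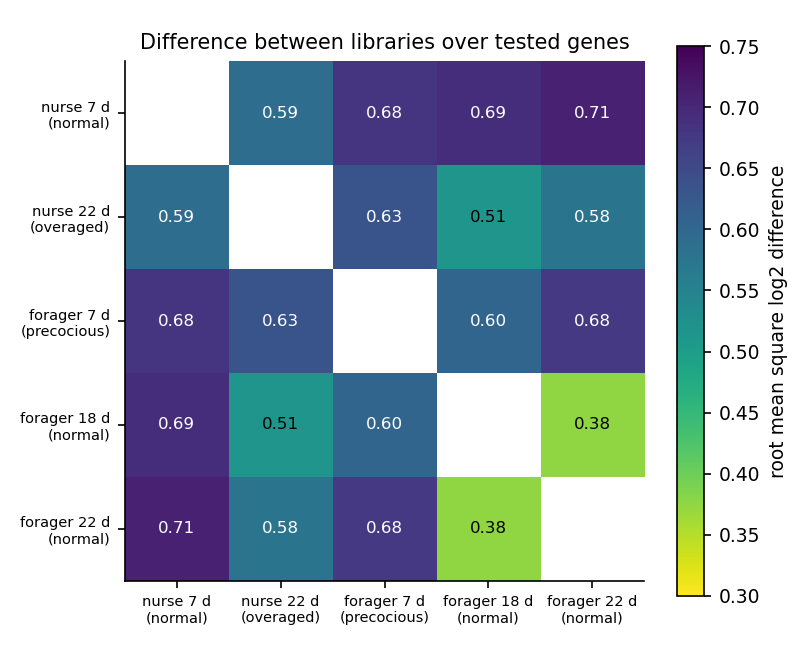
Root mean square log2 difference between each pair of the 5 head libraries over 7758 genes, from TMM-scaled RPKM plus 1; darker cells mark larger differences. The 18-day and 22-day normal foragers differ least (0.375) and the 7-day nurses and 22-day normal foragers most (0.709).

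The first question was which genes differ between nurses and foragers whatever their age. ACSNU10468 was lower in foragers, at 276 RPKM in the precocious foragers, 193 at 18 days and 129 at 22 days, against 3057 in the 7-day and 1744 in the 22-day nurses. ACSNU04062 was at 17425 RPKM in the 7-day and 10976 in the 22-day nurses, and at 3229, 863 and 474 in the precocious, 18-day and 22-day foragers. ACSNU04778 was higher in foragers, at 67.0, 351 and 452 RPKM in the precocious, 18-day and 22-day foragers, against 6.47 in the 7-day and 50.8 in the 22-day nurses. ACSNU09203 was low in nurses, with 6 reads at 7 days and 3 at 22 days, and had 240 reads in the precocious foragers, 46 at 18 days and 85 at 22 days. Fitted over the 5 libraries with limma, with age class as the other term, the role differences on the log2(RPKM + 1) scale were 3.46 ± 0.30 (SE) for ACSNU09203, 3.05 ± 0.30 for ACSNU04778, -3.46 ± 0.31 for ACSNU10468 and -3.38 ± 0.39 for ACSNU04062. Their Benjamini-Hochberg adjusted p from limma were 2.63e-05, 5.24e-05, 2.63e-05 and 0.000314 on the values as deposited, and 0.0133, 0.00809, 0.00809 and 0.0445 after scaling by the trimmed mean of M-values (TMM).

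On the values as deposited, limma called 54 genes higher and 51 lower in foragers at an adjusted p below 0.05, of 7758 tested. After TMM scaling, 7 were called higher and 5 lower, and all 12 were among the 105 called on the deposited values. The 51 lower genes took 20.1% of the reads of the 7-day nurses and 13.2% of those of the 22-day nurses, against 4.43% in the precocious, 1.47% in the 18-day and 0.770% in the 22-day foragers. Of these shares ACSNU04064 alone, the most abundant gene of both nurse libraries, held 11.1% and 7.48% in the nurses and 2.17%, 0.935% and 0.498% in the same foragers, and the other 50 genes together held 9.06% and 5.69% in the nurses and 2.26%, 0.534% and 0.271% in the foragers. The 5 that were also lower after scaling took 16.1% and 10.6% in the nurses, and ACSNU04064, ACSNU04062 and ACSNU10468, which are 3 of the 5, held nearly all of it, at 16.1% and 10.6%. The 54 higher genes took 0.566% and 3.12% of the reads of the 7-day and 22-day nurses, and 4.55%, 13.6% and 11.4% in the precocious, 18-day and 22-day foragers. ACSNU08899, whose share is given with the most abundant genes, held most of this in each of these libraries except the 7-day nurses, where it held 0.133%. It was called as deposited (log2 difference 3.18 ± 0.44 SE, adjusted p from limma 0.00147) but not after TMM scaling, where the difference was 3.01 ± 0.50 (adjusted p from limma 0.101). Without it the other 53 genes took 0.433% and 0.633% in the nurses and 1.25%, 1.61% and 1.96% in the foragers. The 7 that were also higher after scaling were scarce, with at most 0.0489% of the reads of a library. Of the 105 genes, 31 had another called gene within 5 ID numbers, and how reads shared between similar genes were counted is not given in the sources used here. The count rested on the libraries included: limma called 10 genes without the 18-day foragers and 0 without the 22-day foragers, where 738 had an unadjusted p below 0.05. Without the 22-day foragers the role differences of ACSNU09203, ACSNU04778, ACSNU10468 and ACSNU04062 were 3.43, 2.98, -3.32 and -3.05 on the log2 scale, close to those of the full fit. Their adjusted p from limma without these foragers were 0.0726, 0.0726, 0.0726 and 0.218. Each fit without 1 library had 1 residual degree of freedom, so this number alone does not account for the lost calls. Without a normal forager library, that degree of freedom held only the interaction of role and age. These fits therefore measured role against that interaction. Beyond this, the cause of the lost calls was not tested. Other libraries left out moved some differences more. ACSNU04062 was at -4.10 without the 7-day nurses or without the precocious foragers, and at -2.43 without the 22-day nurses. ACSNU09203 was at 3.00 in the former fits and 4.07 in the latter. Limma called 302 without the 7-day nurses, 307 without the precocious foragers and 748 without the 22-day nurses, fits whose spread came from the 18-day and 22-day forager pair alone.

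**Figure D2:**
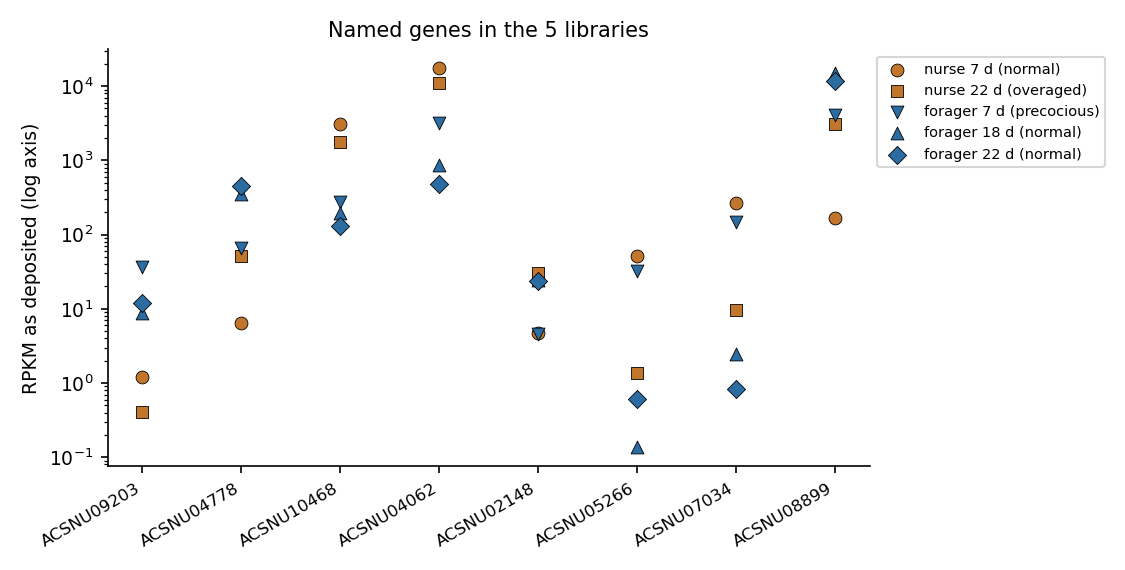
RPKM as deposited, on a log axis, of 8 genes in each of the 5 head libraries; orange symbols are nurses and blue symbols foragers, 1 symbol per library. ACSNU10468 and ACSNU04062 lie higher in both nurses than in the 3 foragers, and ACSNU05266 and ACSNU07034 lie higher in both 7-day libraries than in the 3 older ones.

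Foragers and nurses of the same age were then set against each other. At 7 days, ACSNU10468 was 13.0-fold higher in nurses than in precocious foragers (95% counting interval 12.6 to 13.4), and at 22 days 15.6-fold higher in nurses than in normal foragers (15.0 to 16.3). ACSNU04778 was 8.81-fold higher in foragers at 7 days (5.31 to 15.7) and 7.71-fold higher at 22 days (6.62 to 9.02). ACSNU04062 was 6.34-fold higher in nurses at 7 days and 26.8-fold at 22 days. ACSNU09203 was 25.5-fold higher in foragers at 7 days (11.6 to 70.2) and 25.6-fold at 22 days (8.47 to 127), the wide intervals following from its 6 and 3 reads in nurses. After TMM scaling, 959 genes (12.4%) lay at or beyond a 2-fold difference at 7 days, 522 higher and 437 lower in the precocious foragers, and 497 (6.41%) at 22 days, 118 higher and 379 lower in the normal foragers. On the values as deposited the splits were 785 higher and 233 lower at 7 days, and 230 higher and 281 lower at 22 days, with the median gene shifted by 0.14 and 0.20 on the log2 scale.

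At both ages 43 genes were at or beyond 2-fold higher in foragers and 77 lower, where independent lists of these sizes would share 7.94 and 21.3. A further 32 genes passed 2-fold in opposite directions, against 32.1 for independent lists. The 7-day and 22-day comparisons share no library. Across all 7758 genes, which are not independent replicates, the log2 ratios at 7 and 22 days were weakly correlated, with Pearson's r of 0.126 and Spearman's rho of 0.051. On the values as deposited, 71 genes were higher and 40 lower in foragers at both ages.

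**Figure D3:**
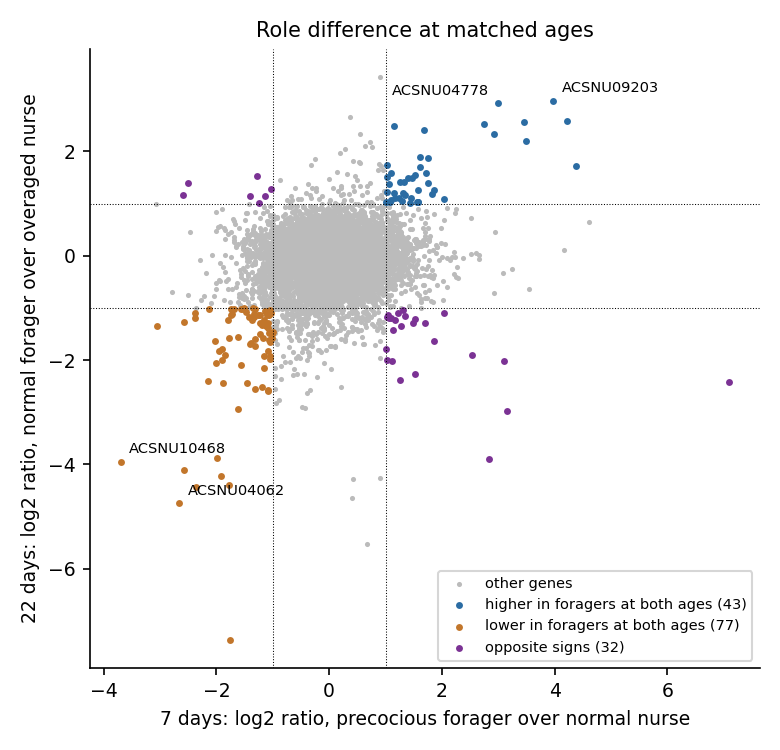
Log2 ratio of foragers over nurses at 22 days against that at 7 days for 7758 genes, 1 point per gene, from TMM-scaled RPKM plus 1; dotted lines mark 2-fold. Coloured points passed 2-fold at both ages: 43 higher and 77 lower in foragers at both, and 32 in opposite directions.

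The usual course of a worker's life, from 7-day nurse to forager, changes age and task together. ACSNU04778 was 39.96-fold higher in 18-day foragers than in 7-day nurses (95% counting interval 24.5 to 70.2) and 45.6-fold higher in 22-day foragers (28.0 to 80.1). ACSNU10468 was 21.5-fold and 36.2-fold lower in the same foragers, and ACSNU04062 was 27.4-fold and 56.3-fold lower. After TMM scaling, 801 genes passed 2-fold in the 18-day foragers, 297 higher and 504 lower, and 784 in the 22-day foragers, 252 higher and 532 lower. On the values as deposited the directions turned, with 770 higher and 242 lower at 18 days and 1060 higher and 205 lower at 22 days, and the median gene was shifted by 0.35 and 0.50 on the log2 scale. Totals without the 50 most abundant genes also turned them, with 499 higher and 338 lower at 18 days and 459 and 341 at 22 days. Median-of-ratios scaling kept the TMM majorities, with 310 higher and 484 lower, and 260 and 515.

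**Figure D4:**
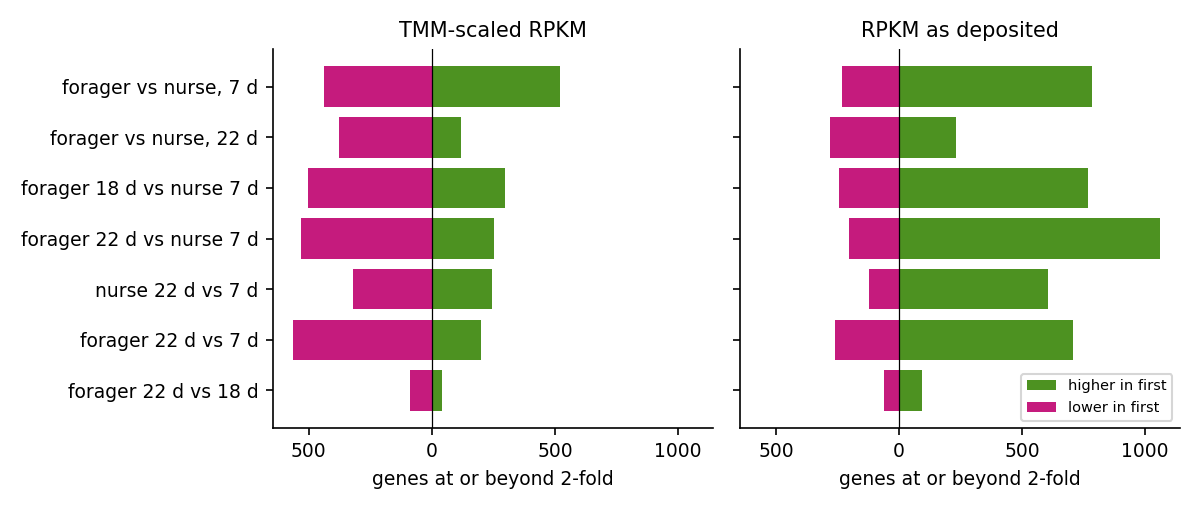
Number of genes at or beyond 2-fold in each of 7 comparisons of a pair of head libraries, of 7758 compared; green bars to the right count genes higher in the first-named library and pink bars to the left genes lower in it, with TMM-scaled RPKM in the left panel and RPKM as deposited in the right panel. Forager against nurse at 7 days gives 522 higher and 437 lower after scaling, and 785 higher and 233 lower as deposited.

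The next question was which genes differ with age whatever the task. ACSNU07034 was at 264 RPKM in the 7-day nurses and 146 in the 7-day foragers, and at 9.66 in the 22-day nurses, 2.44 in the 18-day foragers and 0.832 in the 22-day foragers. ACSNU05266 was at 51.7 and 32.1 RPKM in the 7-day nurses and foragers, with 360 and 298 reads, and had 14 reads in the 22-day nurses, 1 in the 18-day foragers and 6 in the 22-day foragers. ACSNU02148 was higher in older bees of both tasks, at 30.5 RPKM in the 22-day nurses, 24.4 in the 18-day and 23.8 in the 22-day foragers, against 4.78 in the 7-day nurses and 4.61 in the precocious foragers. ACSNU04778, named above for task, was also higher in older bees. On the deposited values limma also called ACSNU07034 lower in foragers, with a log2 difference of -1.55 ± 0.35 (SE, adjusted p from limma 0.0390). After TMM scaling that role difference was -1.67 ± 0.36 and was not called (adjusted p from limma 0.139). With role as the other term, limma put the age differences on the log2(RPKM + 1) scale at -5.34 ± 0.35 (SE) for ACSNU07034, -4.56 ± 0.27 for ACSNU05266, 2.28 ± 0.27 for ACSNU02148 and 2.66 ± 0.30 for ACSNU04778. The adjusted p from limma were 3.86e-07, 2.19e-07, 0.000273 and 0.000146 as deposited, and 0.00159, 0.000623, 0.0146 and 0.00794 after TMM scaling. ACSNU02148 lost its call without the 18-day foragers (adjusted p from limma of 0.0806) and without the 22-day foragers (0.0521), while its log2 difference stayed at 2.30 and 2.31. The age difference of ACSNU07034 ran from -5.87 without the 7-day nurses or without the 22-day nurses to -4.64 without the precocious foragers.

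On the values as deposited, limma called 62 genes higher and 44 lower in bees aged 18 and 22 days than in those aged 7 days. After TMM scaling 5 were called higher and 25 lower, all 30 of them among the 106 called on the deposited values, and the median gene, which lay 0.27 higher in older bees on the log2 scale as deposited, lay at -0.02. The 44 lower genes took 2.80% of the reads of the 7-day nurses and 3.08% of those of the precocious foragers, against 0.458% in the 22-day nurses, 0.219% in the 18-day and 0.223% in the 22-day foragers. Within these shares ACSNU08866 alone held 1.23% in each of the 7-day libraries, and the other 43 genes held 1.56% and 1.85%, against 0.325%, 0.123% and 0.126% in the same older libraries. The 25 lower after scaling took 2.36% and 2.68% in the 7-day libraries and 0.247%, 0.148% and 0.144% in the older ones. Most of this was held by 3 genes with neighbouring ID numbers, ACSNU08866, ACSNU08867 and ACSNU08865. They took 2.05% and 2.47% in the 7-day libraries and 0.175%, 0.119% and 0.120% in the older ones. The 62 higher genes took 0.424% in the 7-day nurses but 3.79% in the precocious foragers, which was more than the 3.61% in the 22-day nurses, and 13.3% and 10.9% in the 18-day and 22-day foragers. ACSNU08899 held most of this too, except in the 7-day nurses, and its age difference of 2.77 ± 0.44 (SE) on the log2 scale, with an adjusted p from limma of 0.00362 as deposited, was 2.43 ± 0.50 after TMM scaling, with an adjusted p of 0.129. Without it the other 61 genes took 0.291% and 0.492% in the 7-day nurses and precocious foragers, and 1.13%, 1.36% and 1.43% in the 22-day nurses, 18-day and 22-day foragers. Of the 106 genes, 24 had another called gene within 5 ID numbers. The age fit without a normal forager library again took its spread from the interaction of role and age alone. Without the 18-day foragers limma called 9 genes and without the 22-day foragers 11, while it called 591 without the 7-day nurses, 391 without the precocious foragers and 643 without the 22-day nurses, again with the spread taken from the 18-day and 22-day forager pair alone.

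Within each task, ACSNU07034 was 36.2-fold lower in 22-day than in 7-day nurses (95% counting interval 31.3 to 42.0) and 229-fold lower in 22-day than in precocious foragers (141 to 402). ACSNU02148 was 4.83-fold higher in the older nurses (3.74 to 6.32) and 3.97-fold higher in the older foragers (3.14 to 5.06). Among nurses 568 genes passed 2-fold after TMM scaling, 246 higher and 322 lower at 22 days. Among foragers 764 passed between 7 and 22 days, 200 higher and 564 lower at 22 days. The deposited values gave 607 higher and 121 lower among nurses, and 708 higher and 258 lower among foragers, with the median gene shifted by 0.33 and 0.34. Totals without the 50 most abundant genes gave 387 higher and 207 lower among nurses, and 622 and 265 among foragers. Median-of-ratios scaling gave 263 and 298 among nurses, and 190 and 583 among foragers, so the majority direction depends on the scaling. In both tasks 20 genes were higher and 83 lower at 22 days, where independent lists would share 6.34 and 23.4, and 39 passed 2-fold in opposite directions, where independent lists would share 26.2. These comparisons share no library either. Across genes their log2 ratios were also weakly correlated, with Pearson's r of 0.133 and Spearman's rho of 0.027.

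The 18-day and 22-day normal foragers differed at or beyond 2-fold in 129 genes (1.66%), 40 higher and 89 lower at 22 days after TMM scaling, or 93 higher and 61 lower as deposited. ACSNU04778 differed by 1.14-fold between them (95% counting interval 1.05 to 1.24), and ACSNU04062 was 2.06-fold lower at 22 days (2.00 to 2.12). This pair, of the same task and nearby ages, stands closest to a replicate in the design.

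In the 4 libraries aged 7 and 22 days, role, age and their interaction form 3 contrasts with the same counting error. After TMM scaling the role contrast passed 2-fold in 316 genes, 115 higher and 201 lower in foragers, and the age contrast in 258 genes, 70 higher and 188 lower at 22 days. The interaction, which in this layout is also the contrast between bees of usual and of altered age for their task, passed it in 156 genes, 38 higher and 118 lower in bees of usual age. As deposited, the splits were 209 higher and 117 lower for role, 266 and 82 for age, and 38 and 119 for the interaction. With totals without the 50 most abundant genes they were 116 and 191 for role, 170 and 104 for age, and 48 and 95 for the interaction.

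The most abundant genes differed between the libraries. ACSNU04064 took more reads than any other gene in both nurse libraries, 11.06% at 7 days (95% exact binomial interval 11.03 to 11.08) and 7.48% at 22 days, against 2.17% in the precocious foragers, 0.935% in the 18-day and 0.498% in the 22-day foragers. ACSNU08899 took the most reads in the normal foragers, 11.97% at 18 days and 9.48% at 22 days, with 3.30% in the precocious foragers, 2.49% in the 22-day nurses and 0.133% in the 7-day nurses. ACSNU07283 led in the precocious foragers with 4.97%, below its 8.46% in the 7-day nurses. By RPKM, ACSNU08866 was the most abundant gene of the precocious foragers, at 19212, and stood at 19264 in the 7-day nurses, 2077 in the 22-day nurses, 1491 in the 18-day and 1517 in the 22-day foragers. The 10 most abundant genes of each library took 34.9% and 23.2% of the reads of the 7-day and 22-day nurses, and 18.8%, 26.9% and 21.6% of those of the precocious, 18-day and 22-day foragers. The means of 29.0% ± 8.25 (SD, n = 2) in nurses and 22.4% ± 4.12 (SD, n = 3) in foragers were not separated by a two-sided exact permutation test (p = 0.4, where the 10 possible splits allow no p below 0.1). All intervals cover counting error only.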

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

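The tests of the 50 most abundant genes, of bees of altered age and of gene length in each library were chosen after the results were seen.

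Genes that passed 2-fold between foragers and nurses at both 7 and 22 days, but in opposite directions, numbered 32 after TMM scaling. Independent lists would share 32.1. Of the 32, 25 were higher in foragers at 7 days and lower at 22 days, and 7 the reverse. Genes that passed 2-fold between 7 and 22 days in both tasks, but in opposite directions, numbered 39. Here independent lists would share 26.2. With 1 library per group, neither difference was tested.

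Like the age ratios within nurses and within foragers, with Pearson's r of 0.133, the log2 ratios of foragers over nurses at 7 and 22 days were weakly correlated across genes. Pearson's r of these role ratios was 0.126. Counting error at low genes as the whole cause is argued against by r = 0.120 among the 3355 genes with at least 1000 reads over the 5 libraries, and gene length by r = 0.135 after the median of each of 50 length bins was removed. The contrast between bees of usual and of altered age for their task had 0.779 times the variance of the role contrast across genes. Both contrasts are built from the ratios at 7 and 22 days, so this value follows from their correlation and spreads and cannot decide on a cause. The contrast of usual and altered age is also, in this layout, the interaction of role and age. A difference tied to altered age and a role difference that changes with age therefore cannot be told apart. Differences between single libraries, of colony or handling for example, stay open and were not tested.

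The share of higher genes among those beyond 2-fold between foragers and nurses was 54.4% at 7 days and 23.7% at 22 days after TMM scaling, a gap of 30.7 percentage points that put the majority on opposite sides; this difference was not tested. As deposited the shares were 77.1% and 45.0%, a gap of 32.1 points, also on opposite sides. With totals that leave out the 50 most abundant genes they were 46.1% and 32.5%, a gap of 13.5 points with lower genes in the majority at both ages.

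The TMM factors differ between libraries, most for the 7-day nurses, whose log2 factor was -0.338. Counting error at low genes is argued against, since the range of the 5 log2 factors among the 3634 genes with at least 100 reads in every library was 87.4% of that over all genes. Gene length stays open: Spearman's rho with length was 0.0778 for the age contrast and 0.109 for the role contrast, but such contrasts can hide trends of single libraries, and rho with each library's deviation from the gene's mean ran from -0.199 in the 7-day nurses to 0.168 in the 18-day foragers. Leaving the 50 most abundant genes out of the totals removed 61.8% of the shift of the 7-day nurses, from -0.338 to -0.129, which is consistent with a few abundant genes taking up reads there. In the precocious foragers the same step changed the shift by -84.7%, that is, it enlarged it from -0.106 to -0.196, so abundant genes do not account for that library's factor; age and task also stay open and were not tested.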

How the results depend on the processing

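The scaling alternatives of the role and age tests, totals without the 50 most abundant genes, limma-voom and the median-of-ratios scaling were chosen after seeing the data; the others were fixed beforehand. Of 105 repeats of the counts of genes under an alternative, 57 stayed within 1.5 times the main count, and 48 did not. Direction does not enter this tally, so counts whose majority turned can be among the 57. Age among foragers, for example, went from 200 higher and 564 lower to 622 and 265 with totals without the 50 most abundant genes. The named genes were picked in the same libraries for their role or age differences, so repeats of them are no independent check. Of 72 repeats of the named genes' role or age differences, 65 stayed past the threshold, 7 fell short of it and 0 changed sign. Of those 7, 1 was ACSNU04062 for role under median-of-ratios scaling (adjusted p from limma of 0.0508), and the others came from leaving out a normal forager library. The 65 include every repeat without the 7-day nurses, the precocious foragers or the 22-day nurses. In those fits limma drew each gene's spread wholly to the common trend, so their passing rests on an assumed spread. The cause of the changes below was not tested. Fewer libraries, other sets of genes and, in limma, a new estimate of the spread enter by construction.

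The role test called 105 genes as reported, 12 with TMM scaling, 5 with median-of-ratios scaling, 45 with totals without the 50 most abundant genes, 14 with no filter, 162 with a filter of 5 RPKM, and with limma-voom 245 on library totals and 25 with TMM. The age test called 106 as reported and 30, 24, 44, 35, 150, 285 and 51 in the same order, of which 150 is within 1.5 times. With a pseudocount of 0.1 they called 83 and 96, and each term alone 71 and 19. Genes called under as deposited, TMM and median-of-ratios scaling together numbered 5 for role and 24 for age. Genes at an unadjusted p below 0.05 in limma moved less for role: 1055 as reported, 953 with TMM and 961 with median-of-ratios scaling. For age they numbered 1435, 943 and 935 in the same order. Limma's prior degrees of freedom, which set how far a gene's spread is drawn to the common trend, were 13.3, 5.47 and 5.32 there. The counts of calls therefore depend on this estimate as well as on the scaling. Leaving out 1 library gave between 0 and 748 role calls, the 0 without the 22-day foragers (738 at an unadjusted p below 0.05 in limma), and between 9 and 643 age calls. Where a task or age class was left with 1 library, that library is assumed to vary like the others.

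A pseudocount of 0.1 raised the counts beyond 2-fold to 1476 for role at 7 days, 873 for role at 22 days, 1203 and 1187 for 18-day and 22-day foragers against 7-day nurses, 971 for age among nurses, 1280 among foragers, 364 for 22-day against 18-day foragers, 219 for the same direction at both ages, and 623, 540 and 416 for the role, age and interaction contrasts. A pseudocount of 5 lowered them, in the same order, to 407, 208, 395, 405, 252, 324, 25, 46, 120, 135 and 54. As deposited, 22-day foragers against 7-day nurses gave 1265, and a filter of 5 RPKM left 60 for 22-day against 18-day foragers.

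The planned edgeR and DESeq2 tests were not run, since the deposited values are RPKM; of methods for counts, limma-voom was the only one run on the recovered reads. The alternatives of the gene lists, which had no matched gene, were not run either. Library totals alone, planned as an alternative for role and age, are the values as deposited. No separate paired test was run. Libraries were matched by age or by task in the pair comparisons, with 1 library per group. Low genes are limited by depth: ACSNU09203 had 3 reads in the 22-day nurses and ACSNU05266 1 read in the 18-day foragers.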

Other observations

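The tests of ID numbers were chosen after the results were seen, and the count of genes particular to 1 library was not planned.

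The precocious foragers had 9 genes at 10 RPKM or more that stayed below 1 RPKM in each of the other 4 libraries. The 7-day nurses, 18-day foragers, 22-day foragers and 22-day nurses had 0 such genes each. No library had a gene below 1 RPKM that reached 10 RPKM in all the others. The 9 genes rest on 1 library, and no replicate of it was analysed here.

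Genes called by limma often had close ID numbers. Of the 106 genes called for age, 24 had another called gene within 5 ID numbers, against a mean of 10.3 and a highest value of 30 in 10000 random sets of tested genes (permutation p = 0.0023). Of the 105 called for role, 31 did, against a mean of 10.1 and a highest value of 28 (permutation p = 0.0001, the smallest the sets can give). After TMM scaling 13 of 30 age genes did (permutation p = 0.0001, the smallest the sets can give) and 3 of 12 role genes (permutation p = 0.0006). If ID numbers follow the order of genes along the genome, which no source used here states, a candidate explanation is that neighbouring genes, such as copies of 1 family, change together; reads shared between similar copies would give the same pattern and were not tested.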
